A study of Mus musculus with 2 samples.

How the data were processed

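Total RNA from peripheral-blood neutrophils of adult C57BL/6J mice, 5 to 6 weeks old, was sequenced in 2 libraries, which the labels number as biological replicates 1 and 2 of a single group. Per the labels, each library was made with a ScriptSeq v2 kit from 100 ng of RNA with a size range of 200 to 1000, after isolation of the cells from blood by a protocol whose text was not used here. Both libraries carry one donor identifier in the labels, and the sex of the animals is given as not collected, so the spread between the 2 libraries may be technical. The series holds no second condition. All comparisons are therefore between gene groups within the libraries, or between the 2 libraries themselves, and no test between conditions was possible.

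The authors deposited 2 gene tables per library, 1 on GENCODE M21 and 1 on the older GENCODE M4 gene models, both on mm10, per the file list deposited with each library. Each gives an expected count and a TPM (transcripts scaled to a fixed total per library) per gene, per the file headers, and the file list names reads aligned to the transcriptome as their parent. A transcript table of the same M21 release gives the percent of a gene's TPM that each of its transcripts takes, per the file headers. The M21 gene table also holds bounds of an interval of each TPM, per the file headers. These bounds were read only to see how firmly an estimate was held. A further deposited transcript table on M21 gives an estimated count and a TPM per transcript and lists the sequencing reads and 1 further file as its parents, with no alignment among them. It is called the alignment-free table here. The program and version behind each table are not given in the sources used here. The file list also names signal tracks for each strand, but the strand setting of the tables is not given in those sources. The transcript tables on M4 were not used here, since M4 served only as a gene-level alternative.

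The M21 gene table was the main table, as the newer release. Gene symbols, biotypes and coordinates (GRCm38, the assembly that mm10 names) came from the GENCODE M21 annotation, and 55536 entries matched a gene in it. A further 26248 entries carried only a number and no gene. They held 37.0 expected counts in replicate 1 and 46.4 in replicate 2, which is 1.63e-04% and 2.16e-04% of the totals, and stayed out of all gene groups. The 97 spike-in entries had 0 counts in both libraries.

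Expected counts summed to 22647028 in replicate 1 and 21471719 in replicate 2 in the main table. With 3 counts as the limit that a count of 0 allows, a gene with no count lies below 0.132 CPM (counts scaled to the library total) in replicate 1 and 0.140 in replicate 2. Such limits and all counting intervals cover counting error only, since reads amplified by PCR are not independent molecules. Expected counts were rounded to whole numbers for the counting intervals, for the TMM factors of edgeR 4.0.16 and for the size factors of DESeq2 1.42.0 (R 4.3.3). Everything else was computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and drawn with matplotlib 3.10.9. Transcript sequences were matched with BLAST+ 2.17.0 at an identity of at least 95% over at least 100 nt.

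The following choices were made before the data were examined. A total of 33 gene lists with 398 entries were fixed, which cover neutrophils and 9 other kinds of blood cell, non-blood tissue, precursor cells and cell division, 3 classes of granule, the NADPH oxidase, receptors for chemoattractants and adhesion, pattern recognition, Fc receptors, transcription factors, early-response genes, cytokines, interferon-response genes, cell death, energy metabolism, ribosomal proteins, common reference genes, non-coding RNAs and sex-linked genes. A gene counted as detected at a TPM of at least 1 in both libraries. List levels are medians of log2(TPM + 1), with a pseudocount of 1, and their percentile among 10000 random lists of the same size from annotated protein-coding genes describes these libraries and is not a p-value. The genes named in the text are the 15 with the highest mean TPM. In each list they are the 4 highest members, the lowest member and up to 3 members under a TPM of 1 in both libraries. Between the libraries they are the 5 higher and the 5 lower in replicate 2 with the largest fold. Genes named outside this rule are marked as chosen after their values were seen. Some genes that meet the rule are not reported here.

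Between the 2 libraries, a gene counted as differing with a TPM of at least 1 in either, at least 50 expected counts in the higher one and a (TPM + 1) fold of at least 2. Named genes with counts in both libraries have an exact conditional binomial 95% interval of their count ratio. Where 1 library had no count, the counts are given without a fold, which departs from the plan of an interval for every named gene. A list's median log2 ratio was set against 10000 random lists matched on mean expression in 20 bins, and lists below percentile 2.5 or above 97.5 are described as shifted. These rules were set once the files had been read: a list needed at least 3 genes with a TPM of at least 1 in either library for a shift, and where a symbol had 2 gene identifiers (Rmrp and Aldoa) the one with the higher TPM was used. Norad was matched through its older symbol 2900097C17Rik. One entry, Ahsp, matched no gene in the annotation and was not analysed here. The procedure was tested on simulated counts for 22028 protein-coding genes: it recovered 81 of 81 eligible genes planted at a 4-fold difference and none of 49 planted at 1.5-fold, and it called 0 of 4053 unchanged genes. The simulation held counting error only and scored genes with a TPM of at least 4 in either simulated library. Between the real libraries, 39.4% of 11713 nuclear protein-coding genes passed a chi-square limit that counting error alone would pass in 5%. The simulation therefore gives no rate of false calls for the real data.

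The alternatives tried were the M4 gene table, the alignment-free table summed per gene, TPM rescaled to the same total over nuclear protein-coding genes, a pseudocount of 0.1, detection at a TPM of 0.1 or 5 or at 10 counts, filters of no minimum TPM or of 5, TMM and DESeq2 scaling, and each library left out in turn. A comparison of the B-cell list without its immunoglobulin genes was added after the data were seen.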

Results

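The data are transcript levels in 2 total RNA libraries from mouse blood neutrophils, the short-lived granulocytes that reach sites of infection first. Both libraries belong to a single group. Their depth was 22647028 expected counts in replicate 1 and 21471719 in replicate 2. Values below are TPM from the main gene table as mean ± SD over the 2 libraries (n = 2) unless a log2 value, a percent or a count is named. No test between conditions applies, and a difference between gene groups is set against the spread between the 2 libraries. That spread does not cover how far the genes within a group differ.

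Short structural RNAs filled most of the TPM scale, while messenger RNAs took most of the reads. Protein-coding genes held 72.6 ± 0.820% of the expected counts but 8.74 ± 0.333% of the TPM. Small nuclear RNAs (snRNAs), the RNA parts of the spliceosome, held 9.85 ± 2.15% of the counts and 69.3 ± 2.02% of the TPM. The class "misc RNA", which holds the signal recognition particle RNAs Rn7s1 and Rn7s2 and the transcription regulator Rn7sk, took 8.93 ± 1.23% of the counts and 14.0 ± 2.89% of the TPM. The average count of an snRNA fell on an effective length of 32.3 nt in replicate 1 and 38.8 nt in replicate 2, against 3144 and 3102 nt for protein-coding genes. TPM divides by this length, so a TPM of 1 is a strict threshold for a messenger RNA here.

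The 15 most abundant genes by TPM were all short RNAs of the spliceosome or the signal recognition particle. Gm22513, an snRNA gene, had the highest mean with 81739 ± 12660 TPM. Rnu2-10, a gene of the U2 snRNA, and its copies Gm24950, Gm23971 and Gm23849 each stood at 65412 ± 15239. In replicate 2 these 4 genes stood above Gm22513, at 76187 against 72787. Rn7s1 and Rn7s2 each stood at 55867 ± 12350. Rnu1a1, a gene of the U1 snRNA, stood at 31206 ± 3838, as did its copies Gm26444, Gm23804, Gm22068, Gm22317, Gm22634 and Gm25679. Gm24265 closed the series with 30680 ± 10967. The equal values within each series are those of copies whose reads cannot be told apart, so the level of any single copy is uncertain. The 10 most abundant genes took 55.1 ± 0.889% of the TPM, and 11.3 ± 0.447% when TPM was rescaled to nuclear protein-coding genes. By expected counts, the 10 leading genes of each library took 18.4 ± 0.402%, and Malat1 and Rn7sk were among them.

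In both libraries 8698 genes were detected, of which 7682 were protein-coding and 103 were lincRNAs. The count was 14006 at a TPM of at least 0.1, 3605 at a TPM of at least 5, and 14222 with at least 10 expected counts in both libraries. The highest protein-coding genes were the alpha-globin gene Hba-a2 (2894 ± 4.07 TPM), the gene model Gm10800 (1237 ± 234, chosen after its value was seen) and S100a9 (1199 ± 107). The level of Gm10800 is uncertain. Its counts were 51806 and 69097 in replicates 1 and 2, but 133399 and 163577 with the alignment-free table. S100a9 encodes a calcium-binding subunit of calprotectin, which fills the neutrophil cytosol.

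Neutrophil markers were high in both libraries, and B-cell markers stood at the same level. All 15 neutrophil markers were detected, with a median of 43.2 ± 1.12 TPM. The calprotectin genes S100a9 and S100a8 reached 1199 ± 107 and 749 ± 52.0. Csf3r, the receptor for granulocyte colony-stimulating factor, reached 254 ± 27, and the chemokine receptor Cxcr2 94.1 ± 6.05. Ly6g, which encodes the surface antigen commonly used to sort mouse neutrophils, was the lowest at 2.10 ± 0.269. All 12 B-cell markers were detected as well, with a median of 41.8 ± 4.02 TPM. The heavy-chain genes Ighm and Ighd stood at 276 ± 20.3 and 82.0 ± 4.60, and the antigen-receptor chain Cd79b at 77.1 ± 4.96. The complement receptor Cr2 was the lowest member at 14.9 ± 2.04. On GRCm38, S100a9 (ENSMUSG00000056071.12) lies on chromosome 3 at 90692632 to 90695721, Csf3r (ENSMUSG00000028859.14) on chromosome 4 at 126024550 to 126044440 and Ighm (ENSMUSG00000076617.9) on chromosome 12 at 113418558 to 113422730.

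The neutrophil list exceeded the B-cell list, the highest of the other blood lists, by 0.05 ± 0.10 log2 units. This difference was smaller than its spread between the libraries and had opposite signs in replicate 1 (-0.02) and replicate 2 (0.12). With the M4 table it was -0.31 ± 0.15, and it was 0.22 ± 0.12 with the alignment-free one. Every later value is that of a whole library, in which these B-cell markers are present.

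By list median, red-cell transcripts came next, at 21.9 ± 0.580 TPM. On the log2 scale their median was 1.03 ± 0.00108 units below the neutrophil list (0.63 ± 0.11 with the M4 table). By single genes the order differs, since Hba-a2 was the highest of all protein-coding genes. The globin genes Hba-a2, Hbb-bs, Hba-a1 and Hbb-bt held 2894 ± 4.07, 852 ± 32.1, 341 ± 22.5 and 179 ± 13.7. Globin copies share reads, and the split between them is uncertain. Of the 10 measured erythroid genes, 3 were under a TPM of 1 in both libraries, among them Klf1 and Epb42. The erythroid transcription factor Klf1 was the lowest at 0.005 ± 0.00707.

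Markers of the other blood cells were lower. The monocyte list lay 3.48 ± 0.07 log2 units below the neutrophil list, an 11.1-fold difference in TPM + 1, with 8 of 12 genes detected. Its highest members were the growth factor receptor Csf1r (7.25 ± 0.700 TPM), the surface antigen Ly6c2 (7.02 ± 0.269), the chemokine receptor Ccr2 (5.57 ± 0.636) and Treml4 (4.02 ± 0.0424). Adgre4 and Ace were among the 4 members under a TPM of 1. The T-cell list lay 3.48 ± 0.09 log2 units below, with 11 of 12 genes detected. The receptor chains Cd3g and Trbc2 stood at 7.18 ± 0.792 and 6.49 ± 0.240, the kinase Lck at 5.18 ± 0.742 and the interleukin-7 receptor Il7r at 4.93 ± 0.0849, while Cd4 was at 0.580 in both libraries. The platelet list lay 3.92 ± 0.07 log2 units below. The platelet chemokines Ppbp and Pf4 reached 8.73 ± 0.0495 and 5.21 ± 0.276, the tubulin Tubb1 5.57 ± 0.361 and the integrin Itga2b 3.35 ± 0.134. Gp1bb, Gp5 and Gp6 were among its 4 members under a TPM of 1, and Gp6 was lowest at 0.335 ± 0.0778.

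Markers of natural killer cells, eosinophils, basophils with mast cells, dendritic cells and non-blood tissue had medians below a TPM of 1. Natural killer genes had a median of 0.365 ± 0.106 TPM, led by the granzyme Gzma (3.33 ± 0.0212) and the receptor Klrd1 (2.29 ± 0.148), followed by Nkg7 (0.995 ± 0.106) and Ncr1 (0.535 ± 0.346). Ncr1, Klrb1c and Gzmb were among 6 members under a TPM of 1, with Eomes lowest at 0.165 ± 0.0212. Among eosinophil genes the lectin Siglecf (2.48 ± 0.205) and the interleukin-5 receptor Il5ra (2.33 ± 0.205) were detected, ahead of Ccr3 (0.870 in both libraries) and Ear1 (0.255 ± 0.163). Prg2, Epx and Ccr3 were among the 6 members under a TPM of 1, and the lowest, Prg3, had no count in either library. Basophil and mast cell genes were all 8 under a TPM of 1, among them Mcpt8, Cpa3 and Fcer1a. Their highest members were Ms4a2 (0.290 ± 0.240), Gata2 (0.285 ± 0.191), Cd200r3 (0.240 ± 0.170) and Cpa3 (0.205 ± 0.148), and the lowest was Mcpt4 with 0 counts. Dendritic genes had 7 of 8 members under a TPM of 1, including Siglech, Ccr9 and Flt3. The lectin Cd209a (1.13 ± 0.184) was detected, Ccr9, Clec9a and Batf3 followed at 0.415 ± 0.0919, 0.405 ± 0.0778 and 0.205 ± 0.0919, and Xcr1 was lowest at 0.005 ± 0.00707. Of the 10 non-blood genes, including Alb, Ins2 and Myh6, none was detected and 6 had no count in either library. Cdh5 (0.0600 ± 0.0849) was the highest of them, followed by Col1a2 (0.0300 ± 0.0424), Gfap (0.0150 ± 0.0212) and Krt5 (0.0100 ± 0.0141), and Nphs1 was among those at 0.

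**Figure D1:**
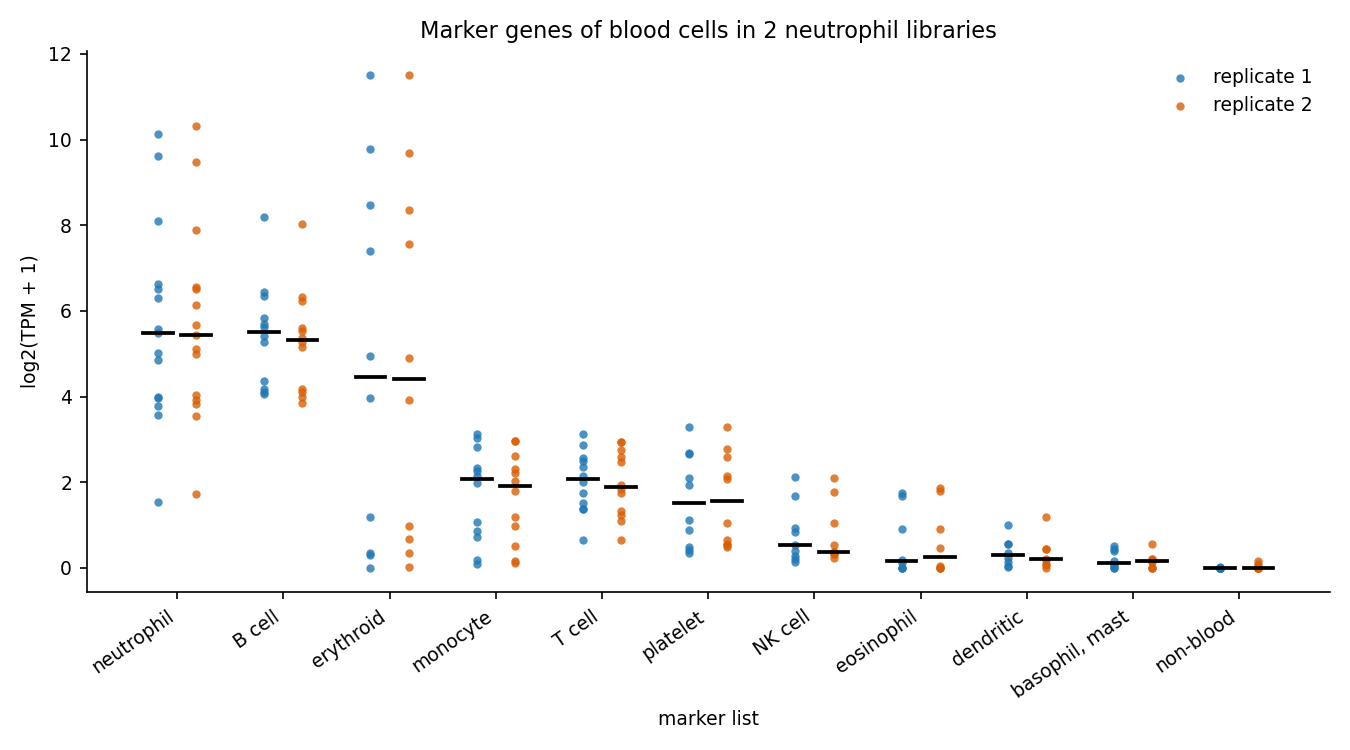
Level of each marker gene, log2(TPM + 1) on the vertical axis, by marker list on the horizontal axis. Each point is a gene in replicate 1 (blue) or replicate 2 (orange) and each black line is the median of the list in that library. The neutrophil medians (5.49 and 5.44) and the B-cell medians (5.51 and 5.32) lie together, above the erythroid medians (4.46 and 4.41) and those of all other lists.

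Medians of the granule lists, whose transcripts are made at successive stages of granulocyte maturation, were graded. The early azurophil list was lowest and the late gelatinase and secretory list highest. Each gene was counted in the granule list fixed for it beforehand. Whether the products, such as those of Lyz2 and Hp, belong to that class alone was not examined here. Of the 7 azurophil genes only Ctsc, the protease that activates the granule serine proteases, was detected (12.4 ± 0.785 TPM), and 6 were under a TPM of 1 in both libraries. The granule serine protease genes Elane and Ctsg and the membrane gene Ms4a3 had 0 counts in both libraries. Myeloperoxidase (Mpo) stood at 0.0600 ± 0.0283, Prss57 at 0.0950 ± 0.00707 and Prtn3 at 0.0150 ± 0.0212. Of the 9 specific granule genes 6 were detected. They were led by the collagenase Mmp8 (21.6 ± 1.87) and the iron-siderophore binder Lcn2 (20.9 ± 0.431), with Cd177 at 3.80 ± 0.424 and Chil3 at 2.56 ± 0.283. Camp, Olfm4 and Ptx3 were under a TPM of 1, and Ptx3 had 0 counts.

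Of the 11 gelatinase and secretory genes 9 were detected. Lysozyme (Lyz2) reached 226 ± 0.806, haptoglobin (Hp) 76.9 ± 2.63, the gelatinase Mmp9 51.6 ± 2.64 and the integrin Itgam 28.7 ± 1.54, while the phosphatase Alpl was the only member under a TPM of 1 in both libraries (0.0800 ± 0.0283). The azurophil median lay 1.54 ± 0.24 log2 units below the specific granule median, a difference of -1.54 on that scale, and the specific granule median lay 2.25 ± 0.12 below the gelatinase and secretory median. Both differences were larger than their spread between the libraries, which does not measure the spread among the genes of a list. The first was -4.34 ± 0.04 with TPM rescaled to protein-coding genes and -4.16 ± 0.12 with a pseudocount of 0.1, since the azurophil genes lie near 0. On GRCm38, Mpo (ENSMUSG00000009350.13) lies on chromosome 11 at 87793581 to 87804413, Mmp8 (ENSMUSG00000005800.3) on chromosome 9 at 7558456 to 7568485 and Lyz2 (ENSMUSG00000069516.8) on chromosome 10 at 117277331 to 117282321.

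**Figure D2:**
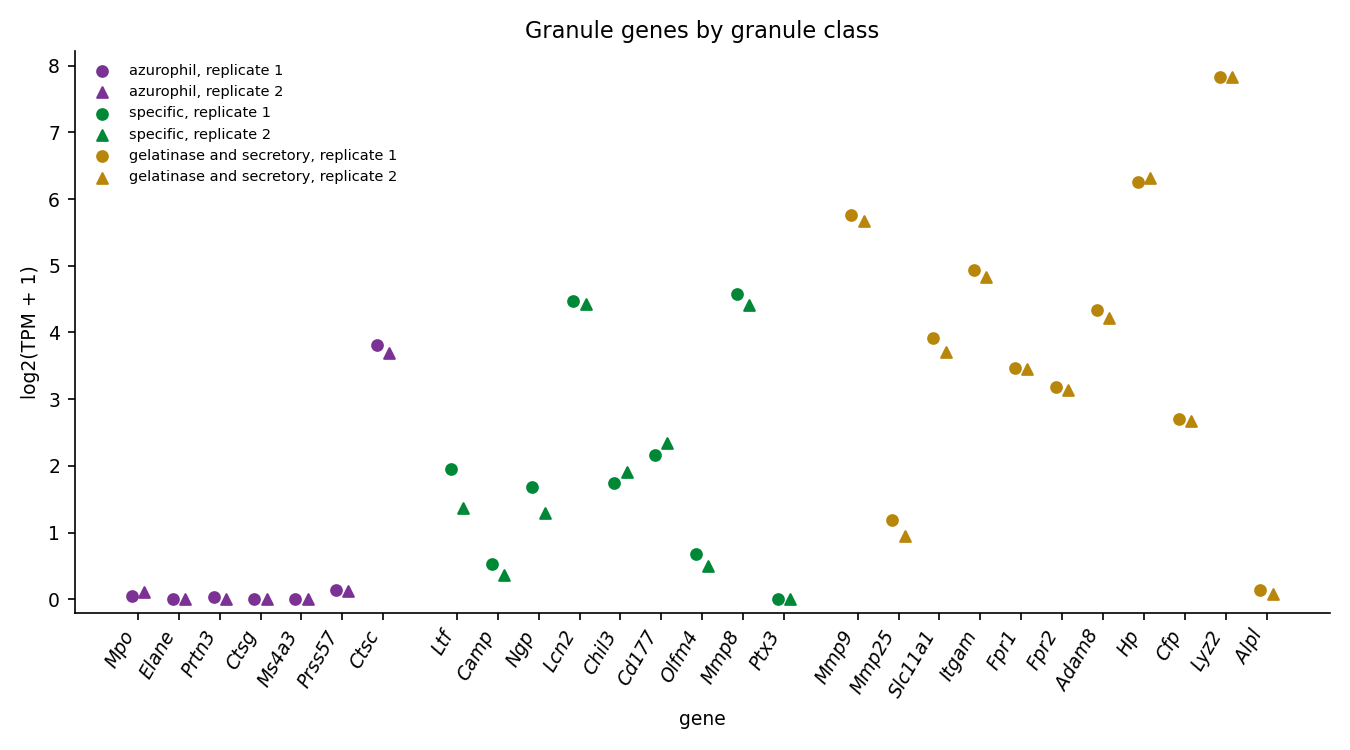
Level of each granule gene, log2(TPM + 1) on the vertical axis, with genes on the horizontal axis grouped and coloured by granule list. Circles are replicate 1 and triangles replicate 2. Azurophil genes other than Ctsc lie near 0, and Lyz2 is the highest gene at 227 and 225 TPM.

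Transcripts for the oxidative burst, chemoattractant reception and adhesion were abundant, and those for Fc receptors and pattern recognition were lower. All 6 NADPH oxidase genes, whose products make the oxidative burst, were detected with a median of 30.4 ± 1.5 TPM. The subunit Ncf1 (36.8 ± 2.35), the GTPase Rac2 (36.3 ± 2.96) and Cyba (24.4 ± 0.0354) lay above Cybb (13.5 ± 0.537). All 15 genes for chemoattractant reception and adhesion were detected, with a median of 28.7 ± 1.54. Cxcr2 stood at 94.1 ± 6.05, the marrow-retention receptor Cxcr4 at 82.1 ± 10.1 and the selectin ligand Selplg at 48.5 ± 0.509, and the leukotriene receptor Ltb4r1 at 1.15 ± 0.0566. Pattern recognition genes were detected in 15 of 19 cases, with a median of 3.99 ± 0.0424. The beta-glucan receptor Clec7a reached 146 ± 6.92, the adaptor Myd88 12.8 ± 0.0354, the inflammasome sensor Nlrp3 12.4 ± 0.820 and the RNA sensor Tlr13 10.9 ± 1.14. Tlr3 (0.0550 ± 0.0354) and Nod2 were the 2 members under a TPM of 1. Of the 6 Fc receptor genes 5 were detected, with a median of 11.5 ± 0.163, Fcgr3 at 57.7 ± 1.34, the shared signalling chain Fcer1g at 34.9 ± 0.481, the inhibitory receptor Fcgr2b at 11.8 ± 0.0849 and Fcgr4 at 11.2 ± 0.410, and Fcgr1 at 0.360 ± 0.0566. Cxcr4, Selplg and Fcgr2b are also transcribed in B cells.

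Of the 15 myeloid transcription factor genes 11 were detected, with a median of 11.9 ± 0.290 TPM. Ets1, a factor also abundant in lymphocytes, led at 60.4 ± 4.96, followed by Klf6 (51.6 ± 2.99), Klf2 (37.2 ± 0.594) and the myeloid regulator Spi1 (32.5 ± 1.17). Cebpa, Cebpe and Gfi1 were among the 4 members under a TPM of 1, with Gfi1 lowest at 0.120 ± 0.0566. All 10 progenitor genes were under a TPM of 1, including Kit, Cd34 and Myb. Myb (0.895 ± 0.0495), Sox4 (0.505 ± 0.0212), Gata2 (0.285 ± 0.191) and Meis1 (0.285 ± 0.0354) were the highest, and Hoxa9 had 0 counts. Of 16 proliferation genes 5 were detected, all of DNA replication. The highest were Pcna (11.4 ± 1.99), Mcm6 (2.54 ± 0.00707), Mcm5 (2.04 ± 0.332) and Mcm3 (2.04 ± 0.516). The division genes Mki67, Top2a and Ccnb1 were among the 11 under a TPM of 1, with Ccna2 lowest at 0.0250 ± 0.0212.

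Il1b and several early-response genes were high, while the cytokine list as a whole had a median of 2.29 ± 0.127 TPM, below the monocyte list (2.99 ± 0.293) and the T-cell list (2.96 ± 0.339). Il1b, the interleukin-1 beta gene on chromosome 2 at 129364570 to 129371139, stood at 619 ± 56.1 TPM, above the chemokine Ccl6 (97.6 ± 6.54), the receptor antagonist Il1rn (15.8 ± 0.580) and oncostatin M (Osm, 8.08 ± 0.141). Of the 17 cytokine genes 12 were detected. Il1a, Cxcl1 and Cxcl10 were among the 5 under a TPM of 1, and Cxcl1 and Il10 had 0 counts. Of the 15 early-response genes 14 were detected, with a median of 15.6 ± 0.467 and the AP-1 genes Fos and Junb at 106 ± 2.60 and 78.5 ± 5.66, the phosphatase Dusp1 at 90.4 ± 2.82 and Btg2 at 51.7 ± 0.368, while Egr1 stood at 0.810 ± 0.0424. All 16 interferon-response genes were detected, with a median of 6.53 ± 0.573. They included the antiviral membrane proteins Ifitm2 (44.0 ± 0.290) and Ifitm1 (36.0 ± 0.417), with Oasl2 (29 ± 2.21) below them, and Usp18 was lowest at 1.92 ± 0.0636. Among 15 cell death genes 13 were detected. The survival factor Mcl1 (127 ± 10.5) exceeded the caspase-8 inhibitor Cflar (14.9 ± 0.891), Casp8 (7.92 ± 0.198) and the pro-death gene Pmaip1 (7.48 ± 0.976), and Bbc3 was lowest at 0.615 ± 0.0212.

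The median of glycolysis genes stood above that of TCA cycle genes by 0.42 ± 0.07 log2 units. This difference was larger than its spread between the libraries and of the same sign in both. All 16 glycolysis genes were detected with a median of 9.56 ± 0.148 TPM. Pyruvate kinase (Pkm, 70.9 ± 1.41), Gapdh (47.7 ± 0.905), Aldoa (38.2 ± 2.61) and Gpi1 (33.8 ± 0.707) were the highest, and the hexokinase Hk2 was the lowest at 2.65 ± 0.0141. All 15 TCA cycle genes were detected with a median of 6.90 ± 0.311. The succinate dehydrogenase subunit Sdha (20.9 ± 0.955), Dlst (13.8 ± 1.48), Idh3g (12.2 ± 0.438) and Mdh2 (11.7 ± 0.658) led, and Idh3a was lowest at 1.22 ± 0.0707. With the alignment-free table the difference was 0.72 ± 0.14.

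Nuclear respiratory chain genes, all 15 detected, had a median of 6.00 ± 0.375 TPM, which was 0.59 ± 0.06 log2 units below glycolysis. Cox6c (16.2 ± 0.643), Cox4i1 (15.8 ± 0.438) and Cox5b (12.8 ± 1.56) were among the highest and Cox5a (2.78 ± 0.0849) was the lowest. Among the 13 mitochondrially encoded genes, mt-Co1 (717 ± 109), mt-Atp8 (551 ± 92.6), mt-Nd3 (124 ± 5.84) and mt-Nd1 (93.5 ± 17.0) were the highest. The genes mt-Nd4l and mt-Atp6 had 0 expected counts in both libraries, and mt-Co2 and mt-Co3 had at most 2.85. Nuclear copies identical in sequence to each of these 4 genes held counts, so their listed levels are uncertain.

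Ribosomal protein genes and common reference genes were all detected. The 16 ribosomal protein genes had a median of 77.3 ± 3.48 TPM, with Rpl7 (146 ± 4.11), Rps4x (116 ± 9.78), Rpl4 (116 ± 8.18) and Rpl8 (97.7 ± 10.9) highest and Rpl10a (36.7 ± 1.99) lowest. Among 12 common reference genes, Actb (686 ± 106), Eef1a1 (426 ± 24.5) and B2m (228 ± 31.8) were highest and Gusb (2.74 ± 0.0141) lowest. Long and structural non-coding RNAs were led by Rn7sk (25675 ± 3342), the RNase P RNA Rpph1 (4165 ± 176), the nuclear RNA Malat1 (1535 ± 59.3) and Rmrp (1408 ± 421). Meg3, H19 and Kcnq1ot1 were the 3 members under a TPM of 1, and H19 had 0 counts. Rmrp is uncertain, since 2 overlapping gene models carry that name and split the reads differently in the 2 libraries.

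Sex-linked genes from both sexes were present in each library. The X-inactivation RNA Xist stood at 6.21 ± 0.177 TPM and its antisense RNA Tsix at 0.0350 ± 0.0212. The Y-linked genes Eif2s3y (17.4 ± 2.26), Ddx3y (8.05 ± 1.10) and Kdm5d (2.90 ± 0.0424) were detected, as was Uty (2.38 ± 0.0212), which was named after its value was seen.

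Messenger RNAs correlated more closely between the 2 libraries than all genes together. Across 9602 genes Pearson's r of log2(TPM + 1) was 0.947 and Spearman's rho 0.931, and across the 8182 protein-coding genes among them they were 0.986 and 0.977. These are correlations across genes, which are not independent replicates.

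At least 2-fold differences were found for 84 of 9097 genes, 51 higher and 33 lower in replicate 2. Small nucleolar RNAs, which guide the modification of ribosomal RNA, made up 30 of them (28 higher and 2 lower in replicate 2), out of 79 that could be compared. The 28 include gene copies that are not separate observations. The U3 copies Rnu3b1, Rnu3b2, Rnu3b3 and Rnu3b4 entered in 2 series of gene models. Counts were equal within each series, at 0 and 259 in the first and 345 and 826 in the second. Protein-coding genes made up 13, out of 8157. With TPM rescaled to nuclear protein-coding genes this count of 13 became 147 (59 higher and 88 lower), as the rescaling raises their TPM against the pseudocount and the threshold. Over all classes, the split was 58 higher and 24 lower with TMM or DESeq2 scaling. The total was 182 with a pseudocount of 0.1 and 235 with the alignment-free table, of which 45 were shared with the main result.

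The genes with the largest fold between the libraries were short RNAs and gene copies, whose values depend on how reads of similar sequences were assigned. In replicate 1 and replicate 2, the U5 snRNA gene Rnu5g had 0 and 222 expected counts, the snoRNA gene Gm23925 0 and 69.6, and 1 of the 2 gene models of the U3 snoRNA gene Rnu3b4 (ENSMUSG00000098641.1) 0 and 259. The snRNA gene Gm24924 had a count ratio of 340 (95% interval 116 to 1653) and Gm25099 of 68.6 (18.6 to 572). In the other direction, the intronic RNA Gm28967 had 1112 and 0 counts, the pseudogenes Gm10240 and Gm13370 274 and 0 each and the histone gene Hist1h2ao 234 and 0. The signal recognition particle copy Rn7s6 had a count ratio of 0.228 (0.222 to 0.234).

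With the alignment-free table, Gm28967 and this model of Rnu3b4 had 0 estimated counts in both libraries. Most of the other differences were smaller there, with 838 and 3096 counts for Rnu5g, 2255 and 2985 for Gm24924, 91.3 and 386 for Gm25099, 72.5 and 1.94 for Gm10240 and for Gm13370, and 193 and 72.0 for Hist1h2ao. Gm23925 had 3.96e-08 and 117 counts and Rn7s6 24189 and 7430. The deposited TPM intervals of the 2 libraries overlap for Rnu5g (0.0113 to 222, and 201 to 1169), for this model of Rnu3b4 (0.00183 to 41.2, and 8.91 to 184) and for Gm10240 and Gm13370. For Gm24924 the interval in replicate 1 (12966 to 22763) lies above that in replicate 2 (6068 to 11569), opposite to the listed values of 1.20 and 368 TPM.

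**Figure D3:**
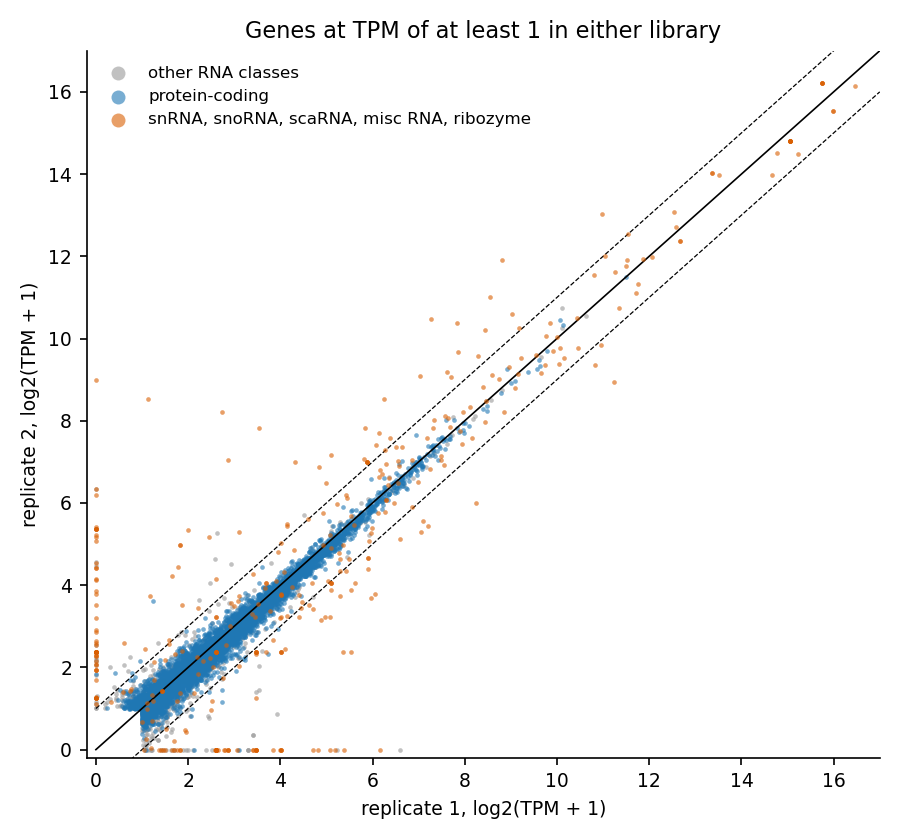
Level of each of 9602 genes in replicate 1 (horizontal axis) and replicate 2 (vertical axis), both log2(TPM + 1). The solid line marks equal levels and the dashed lines 2-fold differences, and points beyond them with fewer than 50 counts are not among the 84 genes counted. Protein-coding genes (blue) follow the line, while snRNAs, snoRNAs and other short RNAs (orange) lie farther from it.

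Of 27 lists with enough expressed members, 2 were shifted between the libraries. If genes varied independently, 1.35 would lie outside the limits by chance. Genes of 1 list may vary together, so neither this number nor the percentiles give a rate of chance shifts. Mitochondrially encoded respiratory genes were lower in replicate 2 by a median of -0.25 log2 units (percentile 0.930), with mt-Co1 at 794 and 640 TPM. Nuclear respiratory genes were higher by 0.07 (percentile 99.8), with Ndufb8 at 6.12 and 9.35, a member chosen after its values were seen. Neither shift held under every setting: without the TPM filter the mitochondrially encoded list lay at percentile 8.05, and with the alignment-free table the nuclear list lay at percentile 96.5 with a median of -0.06. The neutrophil list (-0.02, percentile 86.6) and the B-cell list (-0.13, percentile 23.2) were not shifted. The median of all compared genes was -0.08 and rose by 0.08 with TMM scaling, under which the shifts of the 2 lists were -0.15 and 0.16.

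Among 284 detected list genes, 230 had more than 1 annotated transcript. The leading transcript, by the deposited percent of the gene's TPM, was the same in both libraries for 210 of them. The alignment-free table named the same leading transcript for 177 in each library. Mcl1 was made almost entirely as Mcl1-201 (99.9% and 100%) and Cxcr2 as Cxcr2-202 (99.4% and 99.5%), while Csf3r-201 took 53.0% and 55.1% of Csf3r (39.5% and 40.1% with the alignment-free table). These 3 genes were chosen after their values were seen.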

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

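The test for cells of both sexes was chosen only after the values were seen, as was the split of the second B-cell list by other cell types. For the other tests, the outcome that would count for or against an explanation was written before the test was run, though after the pattern had been seen. Entries of the main table that name no gene held 37.0 expected counts in replicate 1 and 46.4 in replicate 2, summed over 26248 entries.

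B-cell markers stood at the level of neutrophil markers, and a second list of 24 B-cell genes, with no immunoglobulin gene and none from any of the fixed lists, had a median of 42.8 ± 3.96 TPM, which was at least 1.02 times the median of the first B-cell list in both libraries. Its highest members were Cd74 (323 ± 14.2), H2-Ab1 (246 ± 3.10) and H2-Aa (189 ± 5.25), and 12 of its genes are also transcribed in other leukocytes; the other 12, among them Bank1 (57.2 ± 4.70) and Fcer2a (32.7 ± 1.23), had a median of 28.8 ± 1.00. Heavy-chain variable genes with at least 10 expected counts in both libraries numbered 62. The most used, Ighv1-26, held 8.19% and 8.87% of the counts of all 113 annotated heavy-chain variable genes, so many clones may be present. The alignment-free table gave the 12 markers a median of 0.952 of the main value in replicate 1 and 0.945 in replicate 2, where each table was scaled to its protein-coding genes. By the outcome written beforehand, this counted against reads shared with similar genes. Yet both tables assign reads of the same libraries to the same gene models and could divide shared reads alike, so the test cannot decide. B cells carried along in the preparations are a candidate source, and whether the isolation from blood included a step that would remove them is not known from the sources used here.

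The mitochondrial genes mt-Co2, mt-Co3, mt-Atp6 and mt-Nd4l were listed at or near 0 beside abundant mt-Co1. Nuclear pseudogenes on chromosome 1 match them with 100% identity: Gm28661 (mt-Co2) at 24614885 to 24615565, Gm28437 (mt-Co3) at 24613189 to 24613971, Gm10925 (mt-Atp6) at 24613974 to 24614651 and Gm10222 (mt-Nd4l) at 24612407 to 24612700. With a copy on chromosome 2 they held at least 49622 expected counts per library in the main table, so reads of the mitochondrial RNAs may have been assigned to these copies. Whether the mitochondrial RNAs were in the libraries stays open: the alignment-free table gave the 4 mitochondrial genes 15480 and 13857 estimated counts, so the values near 0 do not hold there, and gave them and the copies together at least 55831, but RNA made from the identical copies would give the same sum, which the bound set beforehand did not allow for. No biological explanation was tested.

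Xist and Y-linked genes appeared together in each library. The alignment-free table gave the 4 Y-linked genes a median of 1.13 times the main value in replicate 1 and 1.20 in replicate 2. By the outcome written beforehand, this counted against reads of X-linked relatives as the source of the Y-linked values. Both tables could assign such reads alike, so this test cannot decide either. Xist held at least 4881 expected counts per library, and all 4 Y-linked genes lay above 3 counts in both. Cells of both sexes in each library may account for this, for instance if blood of several animals was pooled; the labels do not say, and a single animal with both signals was not tested.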

How the results depend on the processing

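All of these alternatives except the B-cell list without immunoglobulin genes were planned. The gap between azurophil and specific granule genes and the lead of glycolysis over the TCA cycle kept their direction under every alternative run. Genes detected numbered 14006 at a TPM of 0.1, 3605 at a TPM of 5 and 14222 by counts. They numbered 8267 with the M4 table, 12027 with the alignment-free table and 9043 to 9257 with 1 library alone. With protein-coding scaling, which keeps nuclear protein-coding genes only, 10940 were detected, against 7682 protein-coding genes in the main result. The neutrophil list minus the highest other blood list was -0.31 with the M4 table, 0.22 with the alignment-free table, 0.19 with protein-coding scaling, 0.18 without immunoglobulin genes and -0.02 to 0.12 in single libraries, so no order of the 2 lists holds. Azurophil minus specific granule genes was -1.88 with the alignment-free table, -4.34 with protein-coding scaling, -4.16 with a pseudocount of 0.1 and -1.71 to -1.37 in single libraries. Glycolysis minus TCA cycle was 0.72 with the alignment-free table and 0.37 to 0.47 in single libraries. The share of the 10 most abundant genes was 56.3% with the M4 table, 46.6% with the alignment-free table, 11.3% with protein-coding scaling, which removes the short RNAs by construction, and 54.5% to 55.7% in single libraries. Pearson's r and Spearman's rho were 0.952 and 0.935 (M4), 0.939 and 0.925 (alignment-free), 0.979 and 0.985 (protein-coding scaling), 0.981 and 0.887 (no filter) and 0.914 and 0.900 (TPM of at least 5). With a pseudocount of 0.1, r was 0.890. Genes differing at least 2-fold numbered 235 (alignment-free), 147 (protein-coding scaling) and 182 (pseudocount of 0.1). Of the 2 shifted lists, 1 was left with the alignment-free table (the mitochondrially encoded genes) and 1 without a filter (the nuclear genes). Medians moved upward for 30 lists with protein-coding scaling and for 33 with the alignment-free table. They moved downward for 12 and upward for 1 with the M4 table, and downward for 25 with the smaller pseudocount. The other list differences were counted together with the neutrophil list minus the B-cell list, which is already given above. Of these, 10 moved lower with the M4 table. With protein-coding scaling, 10 moved higher and 1 lower. The numbers were 9 higher and 2 lower with the alignment-free table, and 9 higher and 1 lower with the smaller pseudocount. The cause was not tested where none is named. Depth limits genes under about 10 counts, and with 2 libraries an SD has 1 degree of freedom.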

Other observations

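The groups described here were chosen after their values were seen. Among immunoglobulin constant genes, the heavy chains used before class switching were higher than the switched ones. Ighm and Ighd stood at 276 ± 20.3 and 82.0 ± 4.60 TPM (SD, n = 2), while the switched genes Igha (2.48 ± 0.127), Ighg2b (0.355 ± 0.0778), Ighg3 (0.145 ± 0.120) and Ighg1 (0.0550 ± 0.0636) were low and Ighe had 0 counts. The kappa light chain Igkc, at 372 ± 12.9, exceeded the lambda chains Iglc3 (77.8 ± 0.424), Iglc2 (57.8 ± 7.19) and Iglc1 (35.9 ± 3.78), which share reads. Of 113 annotated heavy-chain variable genes, Ighv1-26 (20.1 ± 0.283) and Ighv1-82 (14.1 ± 0.785) were the highest, and their total was 4514 counts in replicate 1 and 4245 in replicate 2. Other B-cell genes included the homing receptor Cxcr5 at 18.0 ± 0.205, the low-affinity IgE receptor Fcer2a at 32.7 ± 1.23 and the survival receptor Tnfrsf13c at 13.2 ± 0.325.

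Several genes outside the fixed lists were among the most abundant messenger RNAs. The actin-binding peptide gene Tmsb4x stood at 514 TPM in replicate 1 and 485 in replicate 2, the leukocyte phosphatase Ptprc (CD45) at a mean of 222 ± 17.9, the granule proteoglycan Srgn at 170 ± 4.14 and the metabolic regulator Txnip at 169 ± 9.91. The class I antigen genes H2-D1 and H2-K1 stood at 188 ± 8.69 and 160 ± 7.39. Some protein-coding genes differed between the libraries in TPM but hardly in counts. Mapre1 had 12.2 and 3.99 TPM with 2495 and 2209 expected counts, and Klc1 14.5 and 6.61 TPM with 1147 and 1093 counts.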
